A study of Strongylocentrotus purpuratus and Lytechinus variegatus and Patiria miniata with 3 samples.

How the data were processed

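Single-cell libraries of 3 ovaries, 1 per species, were analysed: S. purpuratus and P. miniata, kept at 16 °C, and L. variegatus, kept at room temperature. Per the labels' protocols, the tissue was placed in a hyalin extraction medium for 15 min, sheared, passed through a mesh of 40 micron and loaded on the 10x Genomics Chromium system with the 3′ version 3 chemistry. The deposited matrices hold raw UMI counts per gene and barcode, as whole numbers. They were made with Cell Ranger 6.1.2 for S. purpuratus and Cell Ranger 3.1.0 for the other species, per the file headers. Cell Ranger and Seurat are named in the submitters' processing notes. The genome builds, the annotations and any filter on barcodes are not given in the sources used here. Every barcode present was used, and the barcode and feature lists gave names only. The use of different versions of Cell Ranger, and of different lowest depths per barcode, can alter the numbers of barcodes and the median depths.

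The S. purpuratus features included 341 names, 30897 identifiers without a name and 1024 tRNA features. A table of the assembly Spur_5.0 matched 21089 of 32262 features, or 65.4%, by symbol or gene number; since the annotations differed, no coordinate was taken from it. L. variegatus and P. miniata had 0 named features, and at most 2 identifiers in each direction were printed for each. Of the lists fixed beforehand, the meiosis, stress, mitochondrial genome and muscle lists matched no feature, and the germ cell list matched vasa and Nanos2. The comparison of read-out lists between germ-cell-like and other cells, their course along germ-cell-like clusters, the co-detection of germ line and meiosis genes, and the comparison of genes with the same symbol between species were therefore not made.

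Cells with at least 200 genes were kept. Scrublet, as in Scanpy 1.11.5, called 0 doublets in each library where 7.55%, 10.9% and 13.5% were expected from the loading rate; a caller that marks fewer than 0.5% of more than 5000 cells was taken not to have worked, so no doublet was removed. No limit was set on the mitochondrial share. Counts of genes found in at least 3 cells were scaled to 10000 UMIs per cell and log-transformed. The 2000 most variable genes without the read-out lists, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 0.5 with seed 0 (igraph 0.11.9). Clusters were numbered by size. The largest cluster of S. purpuratus, which was also the shallowest, was the reference for ratios. A cluster took the name of a list when at least 3 of its symbols, as fixed beforehand, had at least 3 UMIs and a CPM at least 2 times that of the other cells, and at least 1 of them was among its 10 features of largest fold. vasa, Nanos2 and GATAc were not among the variable genes.

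UMIs were summed over cells and given as CPM with exact Poisson intervals; ratios of CPM have exact conditional binomial intervals and shares Clopper-Pearson intervals, all at 95% (SciPy 1.17.1). A count of 0 was given the limit of 3 counts where a floor is printed. Shares of cells with a UMI were compared after thinning each cell without replacement to 1000 UMIs. Log2 folds of lists used a prior of 10 CPM, and percentiles refer to 10000 random lists, each member replaced by a feature within 100 ranks in total UMIs. With 1 library per species no test was made, and cells were not used as replicates.

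The named genes followed a rule by size alone: the up to 4 matched members of each list with the most UMIs, of at least 20; germ line, yolk and sperm genes wherever matched; and identifiers as above. The groups, lists of markers, filters, clustering settings, intervals and alternatives were set before the data were examined. Names spelled otherwise in the files were added after the data were examined, as were the rule for the naming of clusters, the depth limits of 5000, 10000, 20000 and 50000 UMIs, the ratios to cluster 1, the choice of clusters 2, 3 and 6 for a closer account, and the tests in the closing section. The rule for naming, the test of vasa in the closing section and the test of a few genes taking most of the counts replaced earlier versions whose values had been seen. Ets4, hnf6, otx and the collagen genes, which lead clusters, were named after their values were seen. For L. variegatus, the features DR311_mgr01 and DR311_mgr02 were printed in place of the lower identifiers given by the rule. The result of 1 list is not reported here. The added names were bf, dd185, SRCR12, Tlr1.1, Tlr1.2, AMAS3, AMAS4, SpRunt-1, the COLP genes, snail, MMP14, MMP16, SNAP-25, rab3, op, p160, egf1, EGFIII, CycA and BND. Alternatives were a filter of 500 genes or none, Leiden resolutions 0.25 and 1.0, 4000 variable genes, read-out lists among them, seed 1, and thinning to 500 or 2000 UMIs or none.

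The steps were tested on simulated data. In sums of counts drawn from the S. purpuratus profile with 200 of 8979 genes changed, the median estimate over the true ratio was 0.966 for 50 genes set to 0.25-fold, 0.999 at 0.5-fold, 1.00 at 2-fold and 1.01 at 4-fold, and the intervals held the true ratio for 96.0%, 98.0%, 96.0% and 98.0% of them. Of 3000 simulated cells of 2 types, with 200 genes set 8-fold apart, 99.3% fell in a cluster mostly of their type. The 2 types were split into 4 clusters, so the number of clusters cannot be read as a number of cell types. For 8 transcripts present in the rarer type only as free RNA at a fraction of 0.3, the median ratio between types was 0.301, with a range of 0.278 to 0.408. That ratio was built into the simulation, where the free RNA had the profile of the commoner type. In the data the source of free RNA is not known. The simulated ratio therefore gives no support to free RNA as the cause of ratios to cluster 1.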

Results

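Ovaries of 3 echinoderm species were profiled by droplet-based single-cell RNA sequencing: the purple sea urchin Strongylocentrotus purpuratus, the green sea urchin Lytechinus variegatus and the bat star Patiria miniata. The libraries address which cell states of the ovary these species share and in which they differ. Each species was represented by 1 library, so no difference between species has a replicate check, and no test was made between libraries. Values are counts of unique molecular identifiers (UMIs), or CPM, a gene's UMIs scaled to the same fixed total of UMIs for each set of cells. Brackets hold exact 95% intervals, Poisson for CPM, conditional binomial for ratios and Clopper-Pearson for shares, and these cover counting error only. Free RNA in the droplets, the dissociation and the calling of barcodes add error that the intervals do not hold.

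The S. purpuratus library held 9432 barcodes and 40685897 UMIs, the L. variegatus library 13611 barcodes and 47221334 UMIs, and the P. miniata library 16846 barcodes and 54844151 UMIs. All barcodes of S. purpuratus and P. miniata had at least 200 genes, and 4 of L. variegatus did not, which left 13607 cells. The median cell held 806.5 UMIs and 516 genes in S. purpuratus, 1052 UMIs and 506 genes in L. variegatus, and 2105 UMIs and 983 genes in P. miniata. The shallowest barcode held 500, 810 and 1387 UMIs in the same order, so the libraries were delimited at different depths. After thinning to 1000 UMIs, which left out 5582 cells of S. purpuratus, 5972 of L. variegatus and none of P. miniata, the median numbers of genes were 613, 486 and 575.

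Barcodes of very high RNA content held a larger share of the UMIs in both sea urchin libraries than in the sea star library. The deepest 1% of cells held 35.7% of all UMIs in S. purpuratus, 40.1% in L. variegatus and 11.9% in P. miniata. When only barcodes of at least 1387 UMIs were counted in every library, these shares were 24.4%, 25.8% and 11.9%. At that common floor, 21.6% [20.2 to 23.1] of 2969 S. purpuratus barcodes held more than 10000 UMIs, against 12.1% [11.1 to 13.1] of 4257 in L. variegatus and 3.68% [3.40 to 3.98] of 16846 in P. miniata. A mesh of 40 micron was used for all 3 ovaries, and it limits the size of the oocytes that could enter a droplet. Species, animal, barcode calling and library were confounded in each of these comparisons, and tank temperature in those with L. variegatus.

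Clustering each library separately gave 7 clusters in S. purpuratus, 7 in L. variegatus and 9 in P. miniata. In S. purpuratus, cluster 1 was the largest and the shallowest, with 4449 cells (47.2% [46.2 to 48.2]) and a median of 625 UMIs. Cluster 4 (768 cells) and cluster 5 (445 cells) were the deepest, with medians of 5177.5 and 11466 UMIs. In L. variegatus, 59.2% [58.4 to 60.0] of cells lay in a cluster with a median of 930 UMIs, and 225 cells (1.65% [1.45 to 1.88]) formed a cluster with a median of 50258 UMIs. In P. miniata the medians of the 9 clusters lay between 1759 and 3167.5 UMIs, and its 21 barcodes above 50000 UMIs lay in cluster 5, whose median was 1815.5 UMIs.

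**Figure D1:**
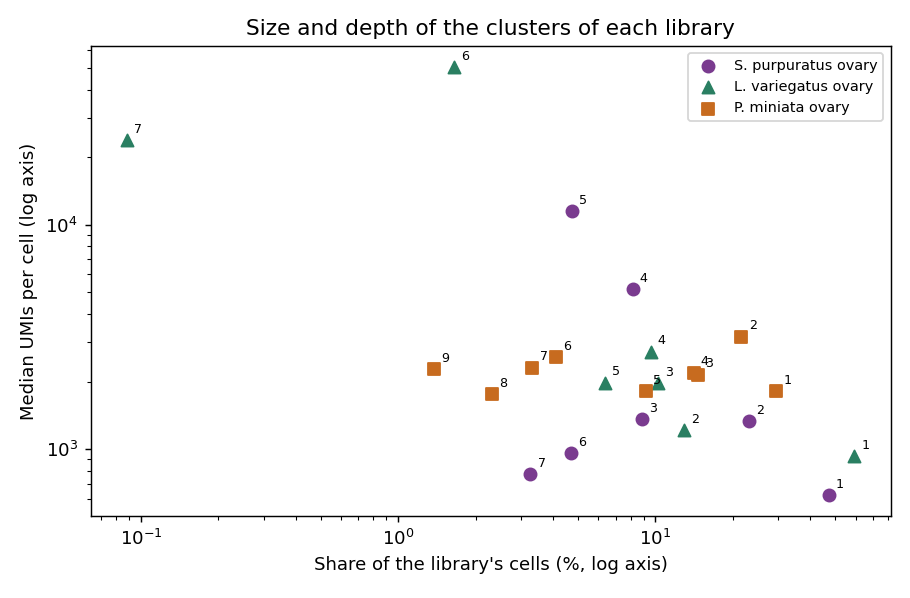
Each point is a cluster of 1 library, with its share of that library's cells in percent on the x axis and its median UMIs per cell on the y axis, both on log axes; the number beside a point is the cluster's number. The L. variegatus cluster of 225 cells has a median of 50258 UMIs, and the deepest P. miniata cluster has a median of 3167.5 UMIs.

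The features of L. variegatus and P. miniata carried only identifiers, and no symbol was shared between the annotations of any pair of species. Expression of the same gene was therefore not compared between species, and clusters of these libraries keep their numbers. L. variegatus cluster 2 was defined by LOC121420035, with 2735 CPM [2673 to 2797] against 16.3 CPM elsewhere, and cluster 5 by LOC121411748, with 370 CPM [348 to 393] against 3.29 CPM. The feature DR311_mgr01 held 5.01% of all L. variegatus UMIs and DR311_mgr02 held 1.68%, and both were low in the deep cluster 6, at 4626 CPM [4595 to 4658] and 1723 CPM [1704 to 1742]. These tagged features were chosen after their values were seen. They took the place of the lower identifiers that the rule by size gave for L. variegatus, which are not printed. In P. miniata, LOC119731435 defined cluster 9 (455 CPM [400 to 515] against 14.5 CPM) and LOC119735355 cluster 4 (727 CPM [709 to 746] against 30.8 CPM). LOC119726513 was low in P. miniata cluster 3, at 0.0284 times its level elsewhere [0.0207 to 0.0381], and LOC119738709 in cluster 5, at 0.0301 times [0.0258 to 0.0348].

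In S. purpuratus, where 341 features carried gene names, vasa and Nanos2 were the only matched germ cell markers, so no cluster was named germ-cell-like. The RNA helicase vasa (gene16864), a germ line gene, was detected with 9352 UMIs and was highest in cluster 4, at 406 CPM [393 to 420], and lowest in the deepest cluster 5, at 118 CPM [112 to 123]. After thinning to 1000 UMIs per cell, a vasa UMI was found in 36.2% [32.5 to 40.0] of cluster 4 cells, 11.6% [8.79 to 15.0] of cluster 5 cells and 21.7% [20.4 to 23.0] of all 3850 cells. The immune-cell-like cluster 3 and the collagen-expressing cluster 6 serve as background, and vasa was found in 17.3% [14.1 to 20.8] and 17.4% [12.5 to 23.3] of their thinned cells. The share in cluster 5 was at or below these shares, and the shares in cluster 4, in cluster 1 (30.03% [26.3 to 33.9]) and in cluster 7 (33.7% [24.3 to 44.1]) lay above them. Free RNA can weigh more in shallow barcodes, such as those of clusters 1, 3 and 6, than in cluster 5. The thinned shares therefore do not show that vasa is absent from cluster 5 or made in cluster 1. Without thinning, 31.5% [30.6 to 32.4] of all cells held a vasa UMI. The share was 70.8% in cluster 5 (median 11466 UMIs), 30.5% in cluster 3 (median 1363 UMIs) and 23.0% in cluster 6 (median 957.5 UMIs).

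Nanos2 (gene26250), a translational repressor of the germ line, was rare, with 364 UMIs in 223 cells. It stood at 16.8 CPM [13.8 to 20.2] in cluster 3, 12.2 CPM [9.97 to 14.7] in cluster 4, 7.28 CPM [5.97 to 8.79] in cluster 5 and 5.57 CPM [3.45 to 8.52] in cluster 1. No Nanos2 UMI was found in the 444 cells of cluster 6, which allows up to 4.11 CPM at 3 counts. Most of the Nanos2 of cluster 3 came from 24 barcodes with more than 50000 UMIs (median 146714), which held 96 UMIs of it in 20 barcodes, or 22.5 CPM. These 24 barcodes held 10.5% of the library's UMIs, and all of cluster 3 held 16.3%. Pooled CPM values of cluster 3 therefore mostly describe these deep barcodes. Their levels of the immune genes c3 and bf were 0.0174 and 0.00685 times those in the cluster's barcodes of at most 20000 UMIs. The 793 barcodes of that cluster with at most 20000 UMIs held 2.85 CPM, so that the ratio was 7.90 [3.27 to 24.9]. The 101 barcodes of other clusters with more than 50000 UMIs held 7.02 CPM, so that the ratio was 3.20 [2.36 to 4.34]. These depth limits were chosen after the values were seen. After thinning to 1000 UMIs, 0.779% [0.526 to 1.11] of all cells held a Nanos2 UMI, with 2.05% [0.944 to 3.86] in cluster 5 and 1.36% [0.625 to 2.57] in cluster 4. Each of these cluster shares rests on 9 cells. When thinned to 2000 UMIs the order was reversed, with 1.43% [0.527 to 3.09] in cluster 5 and 3.89% [2.45 to 5.83] in cluster 4. The thinned shares therefore do not rank clusters 4 and 5. Unthinned, the share was 2.36% [2.07 to 2.69] of all cells. It was 16.6% in cluster 5 (median 11466 UMIs), 10.4% in cluster 4 (median 5177.5 UMIs) and 0 of 444 cells in cluster 6 (median 957.5 UMIs). UMIs of both vasa and Nanos2 were found in 9 of the 3850 thinned cells, with 6.51 given by the product of the shares.

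**Figure D2:**
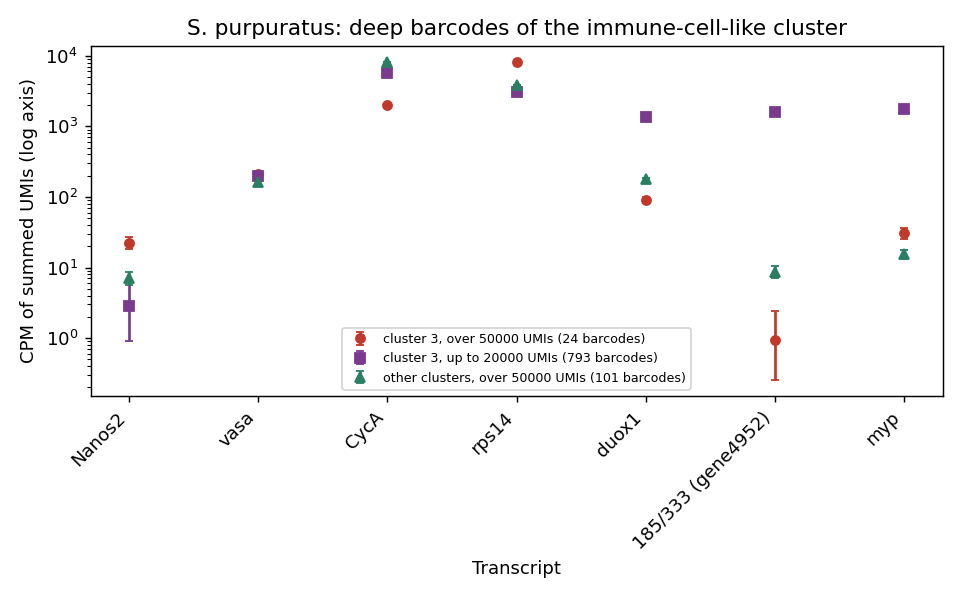
CPM of summed UMIs on a log axis for 7 transcripts in 3 sets of S. purpuratus barcodes, with cluster 3 divided by depth and exact 95% Poisson intervals as bars. The 24 deep barcodes of cluster 3 lie at 22.5 CPM for Nanos2 and at 0.936 CPM for gene4952, and the 793 shallower barcodes at 2.85 and 1582 CPM.

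In S. purpuratus, CycA and egf1 were found in nearly every barcode, and the other egg product genes in 0.975% (EGFIII) to 62.1% (ebr1) of them. CycA (gene21260), a mitotic cyclin that eggs store, was found in 99.6% [99.4 to 99.7] of cells, and egf1 (gene28673), a fibropellin of the egg, in 95.6% [95.2 to 96.0]. CycA was highest in cluster 4, at 16677 CPM [16592 to 16763], and lower in clusters 3 and 6, at 3241 CPM [3198 to 3285] and 3836 CPM [3695 to 3980]; the 793 barcodes of cluster 3 with at most 20000 UMIs held 5635 CPM. The egg bindin receptor gene ebr1 (gene22367) stood at 1254 CPM [1173 to 1340] in cluster 7, 1219 CPM [1196 to 1242] in cluster 4, 323 CPM [310 to 337] in cluster 3 and 314 CPM [275 to 357] in cluster 6; in the 793 barcodes of cluster 3 with at most 20000 UMIs it stood at 550 CPM. Ovoperoxidase, op (gene3239), which crosslinks the fertilization envelope, stood at 654 CPM [637 to 671] in cluster 4 and at 167 CPM [156 to 178] in cluster 2. The deepest cluster 5 held 5919 CPM of CycA and 538 CPM of ebr1, near the levels in the 793 shallower barcodes of cluster 3. It also held 2397 CPM of egf1, 123 CPM of duox1 and 419 CPM of op. Low CycA and ebr1 thus did not set those barcodes of cluster 3 apart from cluster 5. Of the 7 egg product genes, 5 were at least 2-fold lower in cluster 3 than in all other cells and 5 in cluster 6, and none was 2-fold higher in either. In cluster 5, 2 of the 7 were at least 2-fold lower and none was 2-fold higher. Without barcodes over 20000 UMIs, duox1 stood at 2.68 times its level in other cells in cluster 3, and CycA at 0.468 times. The median log2 fold was −1.42 in cluster 3, at percentile 0.09 of 10000 random lists matched on mean expression, and −1.16 in cluster 6, at percentile 0.92; in clusters 1, 2, 4, 5 and 7 the percentiles lay between 19.0 and 86.9. Without barcodes over 20000 UMIs, 3 of the 7 genes were 2-fold lower and 1 was 2-fold higher in cluster 3, with a median log2 fold of −0.98 at percentile 5.73, and 6 were 2-fold lower in cluster 6, with −1.49 at percentile 0.3. These lists were left out of the genes that formed the clusters, and 4 of the 7 names were added to the list after the data were examined.

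Relative to the shallow cluster 1, the egg transcripts CycA, egf1, ebr1, op and duox1 of cluster 6 stood at ratios between 0.267 and 0.373. The intervals of ebr1 and op did not overlap, so the ratios differed by more than counting error. The ratio was 0.312 [0.30 to 0.324] for CycA, 0.322 [0.305 to 0.341] for egf1, 0.267 [0.233 to 0.305] for ebr1 and 0.373 [0.310 to 0.445] for op. In the barcodes of cluster 3 with at most 20000 UMIs the ratios of CycA, egf1 and ebr1 were 0.459 [0.449 to 0.469], 0.451 [0.437 to 0.466] and 0.468 [0.436 to 0.502]. These barcodes combined unlike cells, since at Leiden resolution 1.0 most of cluster 3 lay in a cluster with 3657 CPM [3540.4 to 3777] of CycA and a cluster with 8651 CPM [8451 to 8854], over their 435 and 406 barcodes of at most 20000 UMIs. The dual oxidase gene duox1 (gene6917), a source of hydrogen peroxide, differed there, with a ratio of 2.85 [2.68 to 3.03] and 1353 CPM in these barcodes against 460 CPM [444 to 477] in the whole cluster, while in cluster 6 its ratio was 0.337 [0.277 to 0.407].

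**Figure D3:**
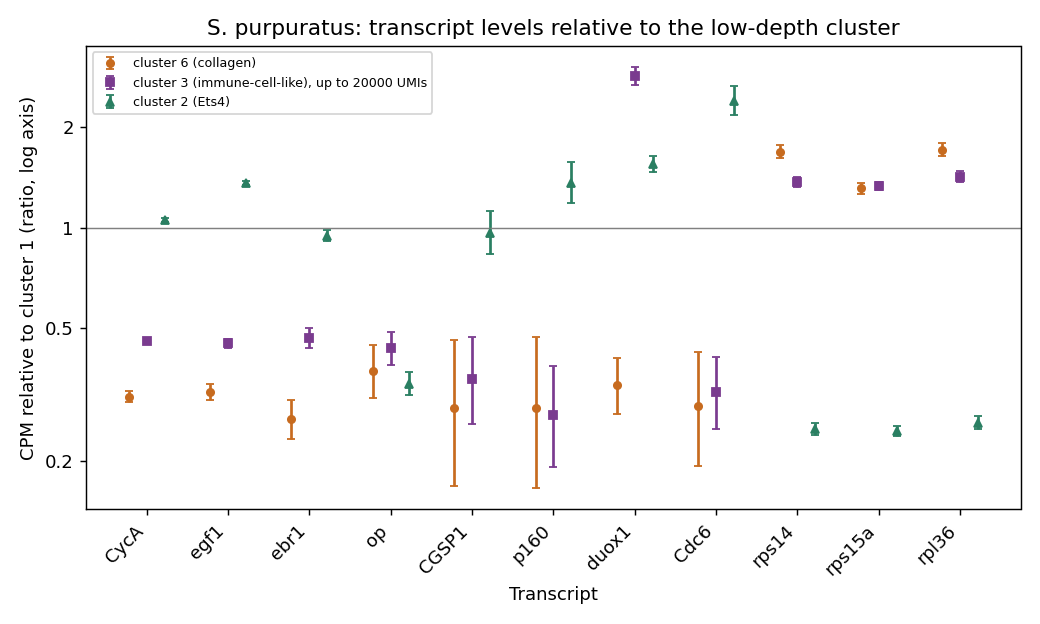
CPM of 11 transcripts relative to cluster 1 of S. purpuratus, as a ratio on a log axis, for clusters 6, 3 (barcodes of up to 20000 UMIs) and 2; bars are exact 95% intervals of counting error. The egg transcripts drawn for cluster 6 lie between 0.267 and 0.373, duox1 of cluster 3 lies at 2.85 and rps14 of cluster 2 at 0.25.

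S. purpuratus cluster 2, with 2183 cells (23.1% [22.3 to 24.0]) and led by the transcription factor genes Ets4, hnf6 and otx, had high levels of Cdc6 and egf1 and low levels of the 3 matched ribosomal protein genes. The replication licensing gene Cdc6 (gene24734) stood at 326 CPM [311 to 342] there, 3.94 times [3.71 to 4.18] its level in other cells, and egf1 at 1.86 times [1.84 to 1.88]. All 3 ribosomal protein genes were at least 2-fold lower, with rps14 (gene31789) at 564 CPM [544 to 584], 0.157 times [0.152 to 0.163] its level in other cells, or 0.275 times without barcodes over 20000 UMIs. Their median log2 fold of −2.65 lay at percentile 47.4 of random lists matched on mean expression. Most features carried no name, so unnamed ribosomal protein genes may be among the random members. The percentile therefore cannot show whether the list stood apart. Of the 7 egg product genes, 2 were at least 2-fold higher and 1, op, lower in cluster 2, and without barcodes over 20000 UMIs none was higher. The fold of op was 0.389 [0.363 to 0.416], and it was 0.127 with at least 500 genes per cell and 0.0773 and 0.0771 in the cluster highest in Ets4 at Leiden resolutions 0.25 and 1.0. In cluster 3 all 3 ribosomal protein genes were at least 2-fold higher (percentile 92.4), and in clusters 4 and 7 all 3 were at least 2-fold lower (percentiles 7.87 and 45.6). In clusters 1, 5 and 6 none differed 2-fold (percentiles 52.2, 46.7 and 98.3). Without barcodes over 20000 UMIs none of the 3 differed 2-fold in clusters 3, 4 and 7, with rps14 at 1.89 times in cluster 3, while all 3 stayed 2-fold lower in cluster 2 (percentile 16.9). Then 2 of the 3 were 2-fold higher in cluster 6 (percentile 98.7) and 1 in cluster 5 (percentile 82.8). Among barcodes of 5000 to 10000 UMIs, 152 of cluster 2 and 113 of cluster 5, the ratio of cluster 2 to cluster 5 was 0.0705 [0.0609 to 0.0811] for rps14, 0.0636 [0.0573 to 0.0704] for rps15a and 0.0859 [0.0752 to 0.0978] for rpl36. In the same barcodes it was 3.78 [3.0 to 4.81] for Cdc6, 1.96 [1.90 to 2.03] for CycA, 4.77 [3.97 to 5.75] for duox1 and 0.134 [0.104 to 0.169] for op. The median of this ratio over 2660 features was 2.23 (quartiles 1.18 and 3.83). CycA thus lay below the median feature, Cdc6 within the quartiles and duox1 above them. Against the 146 such barcodes of cluster 4, the ratio was 0.184 [0.158 to 0.214] for rps14, 0.268 [0.219 to 0.327] for vasa, 0.808 [0.790 to 0.827] for CycA and 0.971 [0.943 to 1.0002] for egf1. The size of cluster 2 depended on the clustering, since at Leiden resolution 0.25 the cluster with the highest Ets4 level held 1.88% of cells, with rps14 at 0.0342 times its level in other cells, and a cluster of 6798 cells held 142 CPM [134 to 150] of Ets4. At resolution 1.0, clusters of 181 and 1576 cells held 385 CPM [354 to 417] and 341 CPM [320 to 362] of Ets4, and each of the other 11 at most 56.1 CPM. The smaller held 118 CPM [101 to 136] of rps14 and 31.6 CPM [23.3 to 41.9] of op. The larger held 673 CPM [644 to 703] of rps14 and 199 CPM [184 to 216] of op, so the lowest levels were those of the smaller cluster.

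Cluster 3, with 835 cells (8.85% [8.29 to 9.44]), was the only cluster of S. purpuratus that the markers fixed beforehand named, as immune-cell-like. It was named from gene4952, of the Transformer family of immune effectors of sea urchin coelomocytes, from the complement gene c3 and from GATAc, which are markers and not findings. At Leiden resolution 1.0 the class held 4.96% of cells, and CycA stood at 0.186 times its level in other cells, with 1963 CPM [1927 to 2001] over all 468 cells and 3657 CPM [3540.4 to 3777] over the 435 of at most 20000 UMIs. Several gene models shared the symbol c3, and counts of such copies and of the Transformer family are uncertain, since reads can be split between them. With the 24 deep barcodes included, rps14 stood at 2.58 times [2.55 to 2.61] its level in other cells, but with 4000 variable genes the ratio was 0.854, and CycA and duox1 stood at 0.798 and 3.84 times. Cluster 6, with 444 cells (4.71% [4.29 to 5.15]), was led by the collagen genes COLP1alpha and COLP2alpha, with LOXL2 among its leading genes. It stayed unnamed, because of the connective tissue markers fixed beforehand only SPARC and LOXL2 were detected there.

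Markers of other cell types were scarce in S. purpuratus. The pigment cell gene gcm had 0 UMIs, which allows 0.0737 CPM at 3 counts, and the skeletogenic gene msp130 had 1 UMI. The sperm protein gene bindin, BND, had 5 and 1 UMIs in 2 gene models. FoxJ1, a regulator of motile cilia, had 277 UMIs and its level lay between 5.14 CPM [3.56 to 7.18] in cluster 3 and 15.1 CPM [7.53 to 27.0] in cluster 6. The synaptic genes rab3, with 470 UMIs, and SNAP-25, with 231 and 113 UMIs in 2 gene models, named no cluster. Major yolk protein, myp (gene28593), the storage protein of nutritive phagocytes, had 5755 UMIs and was found at 533 CPM [516 to 551] in cluster 3, or 1756 CPM in its 793 barcodes of at most 20000 UMIs, and at 270 CPM [253 to 287] in cluster 1 and 18.5 CPM [16.4 to 20.9] in cluster 5; it was among the genes that formed the clusters.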

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

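Leaving out barcodes over 20000 UMIs, the names added later and the mean of each cell's CPM were chosen after the data were examined; the other alternatives were planned. Without the setting that applied no filter, which removed no S. purpuratus cell and could move nothing, of 71 comparisons of a gene's ratio with an alternative, 57 stayed within 1.5 times, 13 moved by more without changing direction, and 1 reversed: with 4000 variable genes rps14 in the immune-cell-like class stood at 0.854 times its level in other cells; the cause was not tested. Leaving out barcodes over 20000 UMIs gave 4 of the moves: rps14 to 0.275 times in the Ets4 cluster and 2.21 times in the collagen cluster, and CycA to 0.468 and duox1 to 2.68 times in the immune-cell-like class. With at least 500 genes per cell, 4936 cells of S. purpuratus (median 1775.5 UMIs) and 7118 of L. variegatus (median 1524 UMIs) were left, because the filter removes shallow cells; the Ets4 cluster held 11.2% of cells, the collagen cluster 5.51% and the immune-cell-like class 10.9%, and Nanos2 was found in 0.496% of thinned cells. At Leiden resolution 0.25 there were 4 clusters in L. variegatus and 5 in P. miniata, and the Ets4 cluster held 1.88% of cells. At resolution 1.0 there were 13, 13 and 14 clusters in S. purpuratus, L. variegatus and P. miniata, by the setting's own construction, and the Ets4 cluster and the immune-cell-like class held 1.92% and 4.96%. The Ets4 cluster is the single one with the highest Ets4 level, and at resolution 1.0 another, with 16.7% of cells, was nearly as high. With the read-out lists among the variable genes these shares were 24.1% and 9.97%, and with seed 1 they were 24.0% and 9.88%; the cause was not tested. The share of cells with a vasa UMI was 13.8% at 500 UMIs, 36.2% at 2000 UMIs and 31.5% unthinned, and that with a Nanos2 UMI 0.254%, 1.64% and 2.36%, which follows from the depth. With the added names, the collagen cluster would be named connective-tissue-like, with the same 4.71% of cells. The doublet caller did not work, so the effect of doublets is unknown. The limit on the mitochondrial share and the alternatives for read-out lists in germ-cell-like cells, for germ line and meiosis genes and for genes of the same symbol were not run, because the lists matched too few features. No paired analysis was possible because each species has 1 library and no test was made.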

Other observations

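The tests in this part were all chosen after the results were seen. Among the S. purpuratus immune-cell-like cells, transcripts of immune effectors and of yolk protein were mostly in different cells. Of 527 cells of cluster 3 thinned to 1000 UMIs, 202 held a UMI of myp and 122 a UMI of gene4952 of the Transformer family, but only 10 held both (1.90% [0.914 to 3.46]), where the product of the shares gave 46.8 cells. At Leiden resolution 1.0, 452 of its 835 cells lay in a cluster of 468 cells and 380 in a cluster of 415 cells. Over barcodes of at most 20000 UMIs, the former (435 barcodes) held 2731 CPM [2630.4 to 2835] of gene4952 and 188 CPM [163 to 217] of myp, and the latter (406 barcodes) 32.7 CPM [21.6 to 47.6] of gene4952 and 3579 CPM [3451 to 3711] of myp. Both genes helped to form the clusters, so the separation is described and not tested.

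Egg product and cyclin A transcripts were found in the collagen cluster, whose cells are not expected to make egg products. CycA is a mitotic cyclin, and whether cells of this cluster divide and make it was not tested. Doublets with an oocyte would put these transcripts in a minority of cells, but 88.4% of its 207 cells thinned to 1000 UMIs held CycA [83.2 to 92.4]. This share cannot decide on doublets if the cells make CycA themselves. The egg product ebr1 was found in 27.1% [21.1 to 33.6] of them, which a low level alone can also give. The median ratio to cluster 1 was 0.301 over 8 transcripts, of which EGFIII, CGSP1 and p160 had too few UMIs (0, 18 and 17) to bear on it. None of the other 5 had an interval lying more than 1.5 times off it. Free RNA of a single source is left possible, although the intervals of ebr1 and op did not overlap. In cluster 3 the same check picked out duox1, with a ratio of 2.85 over barcodes of at most 20000 UMIs and 0.968 over all; at Leiden resolution 1.0 such barcodes held 2062 CPM of it in the cluster rich in gene4952 and 417 CPM in that rich in myp, so that it may be made by the former cells. vasa, which was not among these transcripts, stood at a higher ratio in the collagen cluster, 0.502 [0.416 to 0.602], and no biological explanation was tested.

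In the 24 barcodes of cluster 3 with more than 50000 UMIs, Nanos2 was higher than elsewhere. Clumps of immune cells are argued against by gene4952, which stood at 0.000592 [0.000161 to 0.00152] of its level in the shallower barcodes of the cluster. Whether germ line cells are among these barcodes stays open. The ratio of vasa was 1.05 [0.924 to 1.19] to the shallower barcodes and 1.30 [1.2 to 1.41] to other barcodes over 50000 UMIs. The former cannot decide it, because cluster 3 also served as background for vasa. In that comparison CycA, egf1 and ebr1 stood at 0.354, 0.330 and 0.389, and vasa was not lower. Free RNA and clumps of other cells were not tested.

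Ribosomal protein transcripts were low in the Ets4 cluster of S. purpuratus. Among random lists of like abundance their list lay at percentile 47.4, or 16.9 without barcodes over 20000 UMIs. Those random lists may hold unnamed ribosomal protein genes, so the percentiles cannot show whether the list stood apart. The 200 most abundant genes of the library's shallowest barcodes were also low in the Ets4 cluster. They stood at a median of 0.397 times their level in those barcodes (10th percentile 0.219), the lowest median of all S. purpuratus clusters. They too may include unnamed ribosomal protein genes, and depth was not matched. The low levels were thus not shown to be particular to ribosomal protein genes. Among barcodes of 5000 to 10000 UMIs, the rps14 ratio of the Ets4 cluster to cluster 5 was 0.0705 [0.0609 to 0.0811]. To cluster 4 it was 0.184 [0.158 to 0.214]. These values argue against a difference in depth, but only for 152 of the 2183 cells of the Ets4 cluster. At Leiden resolution 1.0, the larger Ets4-rich cluster, of 1576 cells (median 1335.5 UMIs), held 673 CPM of rps14. The smaller, of 181 cells (median 6325 UMIs), held 118 CPM. Shallower cells were not compared at equal depth, so depth stays open for them. A few genes taking most of the counts would lower the other genes alike. But the median ratio to cluster 5 over 2660 features was 2.23 (quartiles 1.18 and 3.83), again only for barcodes of 5000 to 10000 UMIs. What else stays open may be a cell state with little ribosomal protein mRNA, or barcodes that hold nuclei or parts of cells. Neither of these was tested, and the cluster highest in Ets4 held 1.88% of cells at Leiden resolution 0.25.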
